A study of Homo sapiens with 40 samples.

How the data were processed

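Per the labels, NCI-H508 and HCT-15 cells expressing Cas9 were transduced in quadruplicate with a pooled guide library holding 4 guides per target, and each culture was split into arms with over 1500 cells per guide. End arms were harvested after 10 population doublings, while the time tag of the same samples gives 96 h (0 h for baseline). These statements were not reconciled here. Guide cassettes were amplified from 40 ug of genomic DNA with 18 cycles in the first PCR, although the labels' library source names RNA. The labels give 40 libraries in 10 groups of 4, of which 8 are baseline libraries, and separate transductions make the 4 libraries of an arm replicates.

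The only values used were those of the authors' deposited table of comparisons, with 6606 values of each measure for 1101 genes in 6 comparisons. The log2 fold change per gene is the authors' own, and its base of 2 is an assumption, since the file header names only a log fold change. The authors also deposited a z score, a p-value and an adjusted p-value per gene. DESeq2 1.36.0 is named in the submitters' processing notes, and how guides were combined into genes, how libraries were scaled and which filter was used are not given in the sources used here. Such steps set every value: a scaling that takes most knockouts as neutral centres the fold changes near 0, and a guide combination that ignores gene-wide variation can make z too wide. No genome build is named, so no coordinates are given. All comparisons are within this table, no comparison of DMSO with baseline was used, and 0 columns of values per sample were available to the tests.

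The table was checked for internal agreement. The deposited p-value equalled the 2-sided normal p of the z score to within 4.94e-08, and the adjusted p-value equalled a Benjamini-Hochberg adjustment within each comparison to within 1.61e-06. Fold change and z score differed in sign for 206 of 6606 values, 0 of them called, with an absolute z of at most 0.663. Of the gene symbols, 1091 are current in the RefSeq gene table for GRCh38.p14 and 10 matched as older symbols. That table was used for names and for which genes neighbour each other.

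A knockout was called at an adjusted p under 0.05 in the authors' deposited table. The test per guide and the combination of guides planned beforehand could not be run on values per gene, so the authors' gene-level z score and adjusted p took their place. For gene lists, 24 lists of 438 genes were fixed before the data were examined, of which 395 genes are in the table. The 23 lists with at least 4 measured genes were tested, and 1 list was not, with 3 of its 24 genes measured. A list's mean z was set against 100000 random lists of as many genes, 2-sided, with Benjamini-Hochberg adjustment over 138 tests, and the smallest unadjusted p possible was 1e-05. Counts adjusted over the list alone repeat the Benjamini-Hochberg step on the list's own p-values. The test without a list's most extreme gene is strict, because the random lists kept theirs. Genes are not replicates of the experiment, so the list test describes how a list stands among other genes.

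Differences between comparisons were tested as the difference of z scores divided by the square root of 2, against a normal distribution, with Benjamini-Hochberg adjustment over genes. The same was done on the log2 scale, with the error of each comparison taken as the median ratio of fold change to z score over genes with an absolute z above 2. Both tests treat the comparisons as independent. Comparisons within a line share DMSO libraries if DMSO is the reference, so their errors are then correlated. A difference in z also arises where the same fold change has another error, and so calls on both scales are counted separately. Correlations across genes were tested with 10000 permutations of the gene labels, and unchanged groups against shared controls were simulated 1000 times.

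Named genes followed a rule fixed beforehand: per comparison, the 10 called knockouts with the highest and the 10 with the lowest log2 fold change, always 10 fixed genes, among them MAP2K1, MAP2K2, IGF1R, INSR, BRAF, MAPK3 and EGFR, and up to 4 members of each described list. Its condition on guide directions could not be applied. Some genes that the rule selects are not reported here. Differences and recurrent calls were named by the same ranking or by counts, and genes chosen after their values were seen are said to be so.

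Alternatives planned beforehand were adjusted p thresholds of 0.01 and 0.1, an absolute log2 fold change of at least 1, z centred on its median, list tests on the median z, on the mean fold change and without the most extreme gene, differences on the log2 scale, and crossed concentration codes. Added after the data were seen were z divided by its robust SD in each comparison, centred z for differences, and calls on both scales. The procedures were tested on simulated data over 1101 genes. For HCT-15 trametinib C1, 4% of unchanged lists of 15 genes passed an unadjusted p of 0.05, against 9% with a z shift of 1 and 98% with a shift of 3. For HCT-15 trametinib C2 minus C1, a change of log2 1 was called in 64.8% of changed genes on z and in 95.2% on the log2 scale. For NCI-H508 minus HCT-15 trametinib C1 these shares were 95.6% and 99.9%. A smaller change of log2 0.5 was called in 0.85% on z and 10.7% on the log2 scale for the first difference. For the second these shares were 16.1% and 50.0%, so a difference of that size can easily be missed. These simulations of differences took the implied errors as exact, without a wider spread of z. With a simulated null spread of z of 1.4, 56.1 unchanged genes were called on average, and 1.7 after division by the robust SD.

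The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Depth per library is unknown from these values, so precision is given through z scores and implied errors only.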

Results

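Guide RNA abundance was measured in a pooled CRISPR knockout screen of kinases, phosphatases and E3 ubiquitin ligases. The screen used 2 Cas9-expressing human colorectal adenocarcinoma lines, NCI-H508 and HCT-15. NCI-H508 received trametinib, an inhibitor of the kinases MEK1 and MEK2, at 0.005 or 0.01 uM. HCT-15 received trametinib at 0.1 or 0.7 uM, or linsitinib, an inhibitor of the IGF1 and insulin receptors, at 1 or 4 uM. Each line also had DMSO and baseline arms, giving 40 libraries in 10 groups of 4. The series concerns drug resistance, so the comparisons ask which knockouts became more or less abundant under each drug. The values come from the authors' deposited table, which holds 1 summary value per gene for 1101 genes in 6 comparisons, each a drug at a first (C1) or second (C2) concentration code. Counts per guide and library were not analysed here, so the sequencing depth is unknown, no replicate SD can be given and no direction per replicate can be stated.

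A positive log fold change is read here as a knockout more abundant with drug, and the log base is taken as 2. The table states neither of these, nor which dose each concentration code stands for, nor the reference arm, so every direction in the text rests on that reading. The reference is presumed to be DMSO. Knockouts of PLK1, CDK1 and AURKB, mitotic kinases that proliferating cells need, had log2 fold changes from -0.85 to 0.18 in the authors' deposited table, and none of them passed the test in any comparison. These 3 genes were chosen after their values were seen, so they do not test which arm was the reference. A fixed list of 30 mitotic and cell cycle kinases did shift downward in NCI-H508. Its mean z was -1.21 at C1 (adjusted permutation p 0.0215) and -1.05 at C2 (adjusted permutation p 0.0304). An effect was called where the adjusted p in the authors' deposited table was under 0.05.

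In NCI-H508 under trametinib, the knockouts with the highest fold changes were those of STK11, the LKB1 kinase upstream of AMPK. STK11 had log2 fold changes of 3.32 at C1 (z 24.7, adjusted p 1.64e-131) and 4.31 at C2 (z 26.9, adjusted p 1.24e-156) in the authors' deposited table. KMT2D, a histone methyltransferase, was also high at 1.64 and 2.31, as was CBLB, an E3 ligase that acts on receptor tyrosine kinases, at 1.45 and 2.33, in the authors' deposited table. Knockouts of BRAF, which encodes a kinase of the RAF-MEK-ERK cascade, were lower at both codes.

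The authors' deposited table gave log2 fold changes of -1.06 and -1.16 for BRAF at C1 and C2. Of the 16 measured cascade genes, 2 were higher and 3 lower at C1, and 0 were higher and 5 lower at C2, by the authors' deposited table. Adjusted over the list alone, the counts were the same. The members added at C2 were MAP2K2 at -0.83 and MAPK3 at -0.59 in the authors' deposited table. As a list the cascade did not pass, with a mean z of -0.45 and an adjusted permutation p of 0.337 at C1, and a mean z of -1.24 and an adjusted permutation p of 0.0701 at C2. Its median z was above 0 at both codes, 0.311 and 0.176. DUSP6, a phosphatase that inactivates ERK, had 0.91 and 1.63 in the authors' deposited table. Of 15 measured ERK and MAPK phosphatases, 2 were higher and 0 lower at each code, and adjusted over the list alone 6 and 5 were higher. That list did not pass on its mean z, with adjusted permutation p of 0.0589 at C1 and 0.109 at C2, but passed at C1 on its median z (adjusted permutation p 0.0107).

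PI3K-AKT-mTOR negative regulators shifted upward in NCI-H508, with a mean z of 3.53 over 13 genes at C1 (adjusted permutation p 0.00414) and 4.01 at C2 (adjusted permutation p 0.00414). In that list 2 genes were higher and 1 lower at C1, and 3 were higher and 0 lower at C2, in the authors' deposited table. Adjusted over the list alone, 3 were higher and 1 lower at C1, and 4 were higher and 0 lower at C2. The LKB1 and AMPK family of 17 genes also shifted upward, with a mean z of 2.27 (adjusted permutation p 0.0174) and 2.34 (adjusted permutation p 0.0221). It had 3 and 2 members higher and 0 lower, with the same counts adjusted over the list alone. Besides STK11, which belongs to both lists, SIK3 was higher at 0.53 and 0.51 in the authors' deposited table. The 30 mitotic and cell cycle kinases shifted downward, with a mean z of -1.21 at C1 (adjusted permutation p 0.0215) and -1.05 at C2 (adjusted permutation p 0.0304). Its lower members were 4 at C1, among them CDK6 at -1.28 and CDK2 at -0.98, and 2 at C2, MASTL at -0.95 and TLK2 at -0.74, in the authors' deposited table. Adjusted over the list alone, 1 was higher and 6 lower at C1, and 0 were higher and 3 lower at C2.

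Among other knockouts, PPM1F, a phosphatase of CaM kinases, had log2 fold changes of 1.20 and 1.51 in NCI-H508 in the authors' deposited table. LATS1, a Hippo pathway kinase, had 1.07 and 1.24, and the kinase DYRK1A had 1.00 and 1.22, in the authors' deposited table. At C1 the E3 ligase genes MARCHF9 and PEX10 were higher at 0.89 and 0.82 in the authors' deposited table. At C2 IRF2BP2 was higher at 1.28 in the authors' deposited table. EGFR, the epidermal growth factor receptor, fell at C2 (-1.36, adjusted p 0.00564) and was not called at C1 (-0.40, adjusted p 0.647), by the authors' deposited table. TRIB1, a pseudokinase, was lower at -0.95 and -0.93, GSK3A at -0.94 and -0.92, and the E3 ligase KCMF1 at -0.93 and -1.31, in the authors' deposited table. At C1 RNF8 was lower at -1.02, PTPMT1 at -1.01 and CSNK1A1 at -0.86, and at C2 TRPM7 was lower at -1.14, CDK13 at -1.07, UBR4 at -1.03, PIK3CG at -1.02 and PRKCE at -1.02, in the authors' deposited table. MAP2K1, which encodes MEK1, was not called in NCI-H508, at -0.09 and -0.32 in the authors' deposited table. IGF1R and INSR were not called either, with adjusted p of 0.107 and 0.895 at C1 and 0.119 and 0.348 at C2 in the authors' deposited table.

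Over all 1101 genes, 77 knockouts were called at C1 (43 higher, 34 lower) and 90 at C2 (54 higher, 36 lower) in NCI-H508 by the authors' deposited table. The median error implied by the fold changes and z scores was 0.16 log2 units at C1 and 0.19 at C2. Without its most extreme gene no list passed in any of the 6 comparisons (lowest adjusted permutation p 0.253), and on the median z only the mitotic list kept its call at both codes. With each comparison's z divided by its own robust SD, an alternative chosen after the data were seen, the NCI-H508 counts fell to 18 and 21. That scaling ended the calls of PTPMT1, CDK2, KCMF1 and CSNK1A1 at C1, of EGFR, UBR4, PIK3CG, MASTL, MAP2K2 and MAPK3 at C2, of TRIB1 at C2, and of SIK3 and TLK2 at both.

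In HCT-15 under trametinib, knockouts of PPP6C, the catalytic subunit of protein phosphatase 6, were higher, at log2 1.54 at C1 and 5.17 at C2 in the authors' deposited table. Also higher was RFWD2 (current symbol COP1), an E3 ligase, at 0.37 and 3.34, in the authors' deposited table. STK11 had 1.18 and 2.45 in the authors' deposited table. The lowest knockouts were ILK, the integrin-linked pseudokinase, at -1.68 and -3.47, and UBR1, an N-recognin E3 ligase, at -1.43 and -3.07, in the authors' deposited table. PIK3CA, the catalytic subunit p110-alpha of PI3K, had -1.36 and -2.62, and PTPN11, the SHP2 phosphatase, had -1.31 and -1.69, in the authors' deposited table.

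The RAF-MEK-ERK cascade shifted downward in HCT-15 at C1, with a mean z of -2.93 over 16 genes (adjusted permutation p 0.0243), 1 higher and 4 lower. The counts adjusted over the list alone were 2 higher and 4 lower. BRAF had -1.09 and MAPK3 -0.32 at C1 in the authors' deposited table. At C2 the list did not pass (mean z -0.09, adjusted permutation p 0.56), with 2 higher and 2 lower, and 2 higher and 3 lower adjusted over the list alone. There MAP2K1 was higher at 1.00 (adjusted p 0.00202), while BRAF at -0.52 was not called (adjusted p 0.0616) except with z centred, in the authors' deposited table. EGFR was lower at C1 (-1.66, z -18.8) and not called at C2 (-0.44, adjusted p 0.252), and ERBB2, a related receptor, was lower at both codes, at -0.97 and -0.81, in the authors' deposited table. Of 15 ERK and MAPK phosphatases, 4 were higher and 1 lower at C1, and 4 were higher and 0 lower at C2, without the list passing (adjusted permutation p 0.133 and 0.0701). That became 4 and 1 at C1, and 5 and 0 at C2, adjusted over the list alone. Its members DUSP6 (0.50 and 0.91), DUSP7 (0.49 and 2.23) and PPM1A (0.56 and 2.38) were higher at both codes in the authors' deposited table.

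PI3K-AKT-mTOR negative regulators shifted upward in HCT-15 under trametinib, with a mean z of 3.95 at C1 (adjusted permutation p 0.0215) and 3.66 at C2 (adjusted permutation p 0.0174). In it 2 were higher and 1 lower at C1, and 3 were higher and 0 lower at C2, against 4 and 1, and 4 and 0, adjusted over the list alone. The 12 positive PI3K-AKT-mTOR kinases shifted downward at C2, with a mean z of -2.25 (adjusted permutation p 0.0331) and 5 lower, also 5 adjusted over the list alone. These were PIK3CA, AKT1 at -1.37, RPS6KB1 at -1.36, PDPK1 at -1.23 and MTOR at -0.89 in the authors' deposited table. At C1 that list missed the threshold (mean z -2.77, adjusted permutation p 0.068), with PIK3CA, AKT1 at -0.75 and RPS6KB1 at -0.61 lower in the authors' deposited table, and 4 lower adjusted over the list alone, and it passed on its median z (adjusted permutation p 0.0107). The LKB1 and AMPK family shifted upward at C1, with a mean z of 2.92 (adjusted permutation p 0.0248) and 6 of 17 members higher, also 6 adjusted over the list alone, and did not pass at C2 (mean z 1.71, adjusted permutation p 0.139), where 4 were higher, also 4 adjusted over the list alone. MARK2, a microtubule affinity-regulating kinase of that family, had 0.77 and 1.38 in the authors' deposited table. The list of PP1 and PP2A subunits, which also holds PPP5C and PPP6C of related phosphatases, shifted upward at C2. Its mean z was 3.62 (adjusted permutation p 0.0215), with 4 of 11 higher and 0 lower. Adjusted over the list alone, 4 were higher and 1 lower. Without PPP6C the mean z was 1.61 (adjusted permutation p 0.379). At C1 the list missed the threshold (mean z 2.64, adjusted permutation p 0.0896), with 4 higher and 1 lower, the same adjusted over the list alone. At C2 PPP6C led the list, followed by PPP5C at 1.43, PPP2CA at 1.23 and PPP1CA at 1.04 in the authors' deposited table.

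Other knockouts higher in HCT-15 at C2 were CNOT4 at 2.58, SIAH1 at 2.25 and ZFP91 at 2.09 in the authors' deposited table, all 3 being E3 ligases. At C1 the E3 ligases ARIH2 at 1.07, RNF41 at 0.90 and RNF7 at 0.87 and the phosphatases PPM1F at 0.78 and PPP2CA at 0.77 were higher in the authors' deposited table. Lower at C2 were CSK, a kinase that inhibits SRC family kinases, at -2.89, MAEA, an E3 ligase, at -2.74, and MAP2K3 at -1.84 in the authors' deposited table. ANAPC11, a subunit of the anaphase-promoting complex, was at -1.69, BRAP at -1.60 and MAPK14, the p38-alpha kinase, at -1.55 in the authors' deposited table. At C1 PRKCI was lower at -1.30 and BRAP at -1.02 in the authors' deposited table. MAP2K2, IGF1R and INSR were not called at either code, with adjusted p between 0.294 and 0.874 in the authors' deposited table.

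The authors' deposited table called 154 knockouts at C1 (86 higher, 68 lower) and 128 at C2 (76 higher, 52 lower) in HCT-15 under trametinib. The median implied error was 0.07 log2 units at C1 and 0.23 at C2. At C2 the median fold change of all genes was 0.11 log2 units, and with z centred on its median the split became 55 higher and 67 lower. On the median z, 0 lists passed at C2, where 6 lists had an unadjusted permutation p under 0.05, and the cascade, negative-regulator and LKB1 lists did not pass at C1. Division by the robust SD left 66 calls at C2 and ended those of MAP2K1, MTOR, PPP1CA and DUSP6.

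In HCT-15 under linsitinib, knockouts of PPP2CA, the catalytic subunit of PP2A, were higher, at log2 0.46 at C1 and 0.94 at C2 in the authors' deposited table. MARK2 had 0.46 and 0.83, and ARIH2, an E3 ligase, had 0.57 and 0.81, in the authors' deposited table. EIF2AK1, a kinase of the translation factor eIF2-alpha, had 0.45 and 0.77 in the authors' deposited table. The lowest knockouts included VPS29, a retromer subunit with a phosphatase fold, at -0.62 and -0.98, ILK at -0.69 and -0.73, and PTK2, the focal adhesion kinase, at -0.66 and -0.76, in the authors' deposited table.

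Of the 2 drug targets, IGF1R was called higher with small changes of 0.19 at C1 (adjusted p 0.0119) and 0.16 at C2 (adjusted p 0.0492), and INSR was not called (-0.07 and 0.00), in the authors' deposited table. The IGF1R call was lost at C2 when z was centred, and at both codes when z was divided by its robust SD. EGFR, ERBB2 and ERBB3, receptors of the ERBB family, were lower at both codes, at -0.45 and -0.64, -0.36 and -0.41, and -0.23 and -0.36, in the authors' deposited table. Of 54 receptor tyrosine kinases, these 3 were lower and IGF1R higher at each code, without a shift of the list (adjusted permutation p 0.337 and 0.568). Adjusted over the list alone, 1 was higher and 3 lower at C1, and 0 were higher and 3 lower at C2. The 22 genes of insulin and IGF1 receptor signalling did not shift as a list under linsitinib (adjusted permutation p 0.850 and 0.522). In that list 2 were higher and 3 lower at C1, and 2 higher and 4 lower at C2, the same adjusted over the list alone. On the median z it passed only in HCT-15 under trametinib at C1 (median z -1.51, adjusted permutation p 0.00276).

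PI3K-AKT-mTOR negative regulators shifted upward under linsitinib, with a mean z of 1.93 at C1 (adjusted permutation p 0.0215) and 3.83 at C2 (adjusted permutation p 0.0174). Of the 13 members 2 were higher and 0 lower, with the same counts adjusted over the list alone, and STK11, 1 of the 2, had 0.36 and 0.72 in the authors' deposited table. The positive kinases shifted downward at C1 (mean z -1.81, adjusted permutation p 0.0235) and missed the threshold at C2 (mean z -2.13, adjusted permutation p 0.0701). At each code 3 of 12 were lower, also 3 adjusted over the list alone. These were AKT1 at -0.30 and -0.36, AKT2 at -0.29 and -0.43, and RPS6KB1, the S6 kinase, at -0.37 and -0.53, in the authors' deposited table. The LKB1 and AMPK family shifted upward, with a mean z of 1.43 (adjusted permutation p 0.0304) and 2.76 (adjusted permutation p 0.0221), and 3 and 4 of 17 members higher. Adjusted over the list alone, 3 and 5 were higher. MARK3 was among them, at 0.31 and 0.54 in the authors' deposited table.

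RNF7, PTPN12 and CSK were also higher under linsitinib, at 0.52 and 0.63, 0.41 and 0.65, and 0.30 and 0.62, in the authors' deposited table. At C2 EIF2AK4, another eIF2-alpha kinase, was higher at 0.70 and PPM1F at 0.64 in the authors' deposited table. YES1, a SRC family kinase, was lower at -0.41 and -0.61, and CSNK1A1 at -0.44 and -0.66, in the authors' deposited table. At C1 WDR59 was lower at -0.39, NRBP1 at -0.38 and PKN2 at -0.38 in the authors' deposited table. At C2 RNF25 was lower at -0.93, PGP at -0.68, FIG4 at -0.64 and MAP2K3 at -0.59 in the authors' deposited table. MAP2K1, MAP2K2, BRAF and MAPK3 were not called at either code in the authors' deposited table.

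Under linsitinib the authors' deposited table called 65 knockouts at C1 (32 higher, 33 lower) and 118 at C2 (58 higher, 60 lower), with median implied errors of 0.06 log2 units at each code. Division by the robust SD left 43 and 65, and the call of NRBP1 at C1 ended. On the median z, the positive-kinase list alone passed, at C1 (adjusted permutation p 0.0186) and at C2 (adjusted permutation p 0.0163), and each list call was lost without the list's most extreme gene.

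**Figure D1:**
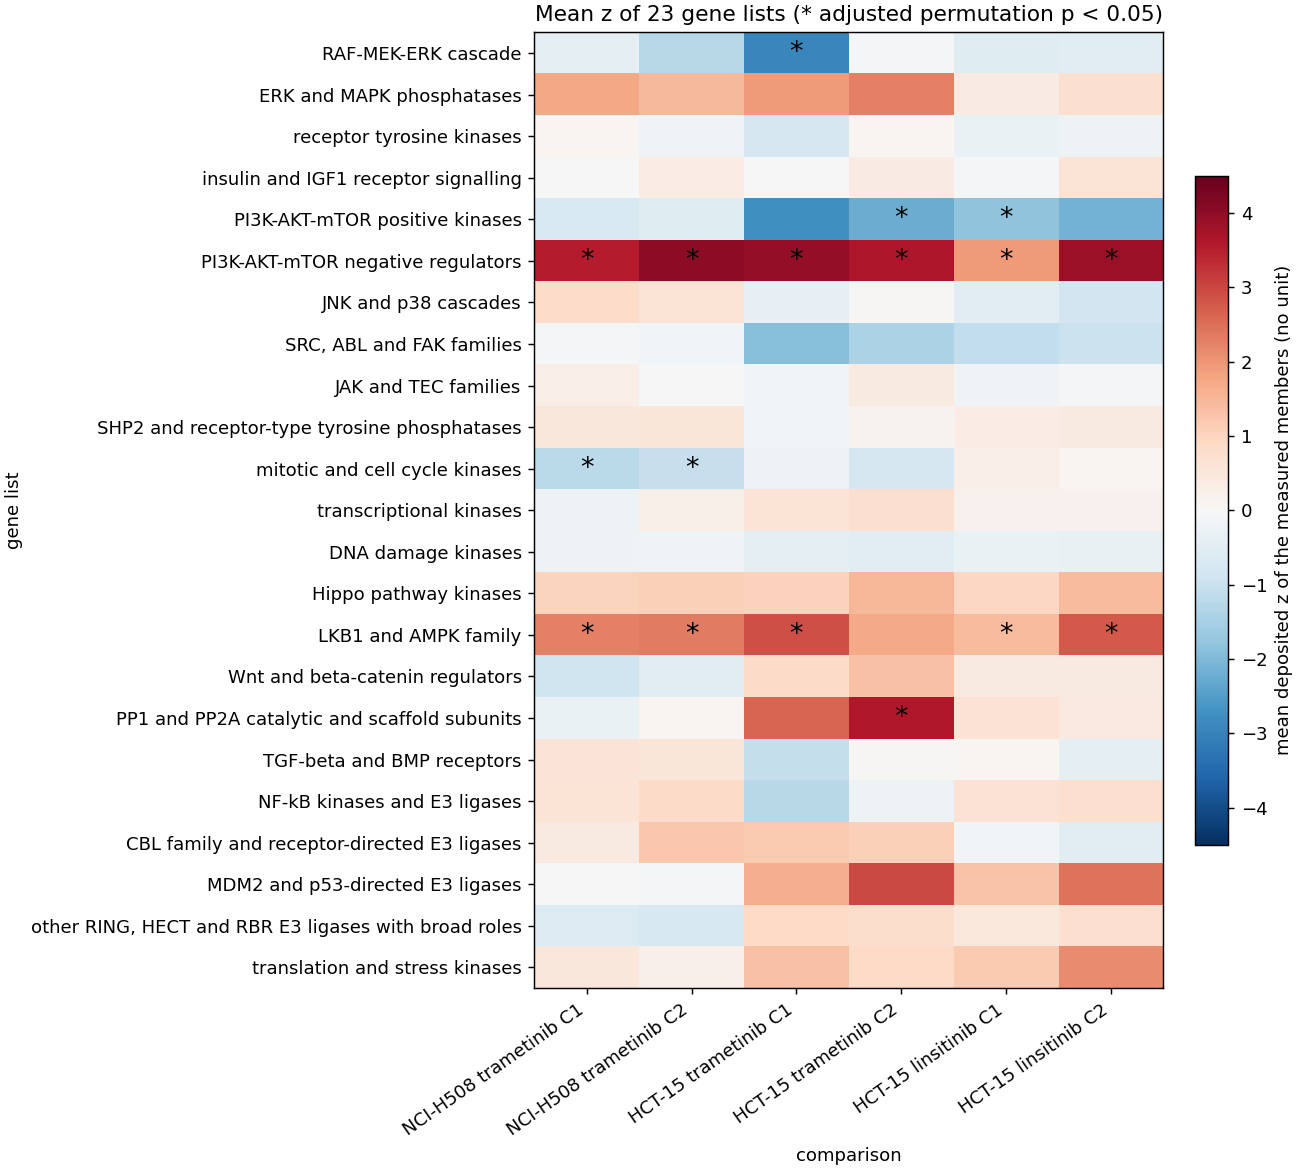
Mean deposited z score (colour, no unit) of the measured members of 23 gene lists (vertical axis) in the 6 comparisons (horizontal axis), with an asterisk where the adjusted permutation p was under 0.05. PI3K-AKT-mTOR negative regulators carry an asterisk in all 6 columns, with mean z from 1.93 to 4.01, and no asterisk remained without each list's most extreme gene.

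The concentration codes were compared next. Here and for drugs and lines, the adjusted p of a difference is that of the z difference. It therefore also depends on the error of each comparison. Knockouts of PPP6C, RFWD2 and CNOT4 rose further at C2 than at C1 in HCT-15 under trametinib, and knockouts of CSK and MAEA fell at C2 with values near 0 at C1. The authors' deposited table gave 1.54 and 5.17 for PPP6C (adjusted p of the difference 1.26e-17), 0.37 and 3.34 for RFWD2 (7.65e-14) and 0.49 and 2.58 for CNOT4 (0.00205). For CSK the values in the authors' deposited table were -0.11 and -2.89 (7.46e-10), and for MAEA 0.03 and -2.74 (1.49e-14). EGFR went the other way, from -1.66 at C1 to -0.44 at C2 (adjusted p of the difference 4.83e-30), in the authors' deposited table. On the log2 scale the adjusted p of that EGFR difference was 1.48e-05. MAP2K4, a kinase upstream of JNK, was called in opposite directions, at 0.19 and -0.67, in the authors' deposited table.

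The test of the z difference called 51 knockouts between the codes in HCT-15 under trametinib, 29 with z higher at C2 and 22 with z lower. Of these, 18 also differed on the log2 scale in the same direction, among them the 6 genes from PPP6C to EGFR just named and MAP2K4. For ILK, RNF7 and STK11 the 2 scales pointed in opposite directions, with larger fold changes but smaller z at C2. Division of z by its robust SD left 24 calls and ended that of CNOT4, and on that scale MAP2K4 itself was called at neither code.

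Under linsitinib, EIF2AK4 knockouts differed between the codes (0.05 and 0.70, adjusted p of the difference 2.44e-15) in the authors' deposited table. PPP2CA and PPM1F were also higher at C2, and RNF25, PGP, PPP1CA and TRPM7 were lower, among 13 differences called on z. All 13 were called on the log2 scale in the same direction, but 2 were left after division by the robust SD, EIF2AK4 among them. In NCI-H508 only 2 differed, IRF2BP2 (-0.25 and 1.28, adjusted p of the difference 4.40e-05) and PPP6C (-0.14 and 1.05, adjusted p of the difference 0.00240), in the authors' deposited table. Neither was called after division by the robust SD, where 4 genes had an unadjusted p under 0.05.

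Across genes, the fold changes at C1 and C2 correlated with Pearson's r of 0.801 in NCI-H508 (Spearman's rho 0.695), 0.705 in HCT-15 under trametinib (rho 0.460) and 0.819 under linsitinib (rho 0.635). The permutation p was 0.0001 for each of 7 relations examined, the smallest the permutations can give, and 0.0001 after adjustment. Genes are not independent replicates, and the codes share DMSO libraries if DMSO is the reference. With no effect at all, sharing such libraries gave simulated r of 0.430, 0.151 and 0.477. The covariances were 0.0944, 0.0909 and 0.0150, against 0.0136, 0.00232 and 0.00168 simulated. The simulation leaves out that drug and DMSO arms come from the same transductions, and the controls could not be split, so part of the excess may come from either. Both codes called 26 genes higher and 17 lower in NCI-H508, 47 and 32 in HCT-15 under trametinib, and 28 and 29 under linsitinib. Independent lists would share 2.11 and 1.11, 5.94 and 3.21, and 1.69 and 1.80.

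**Figure D2:**
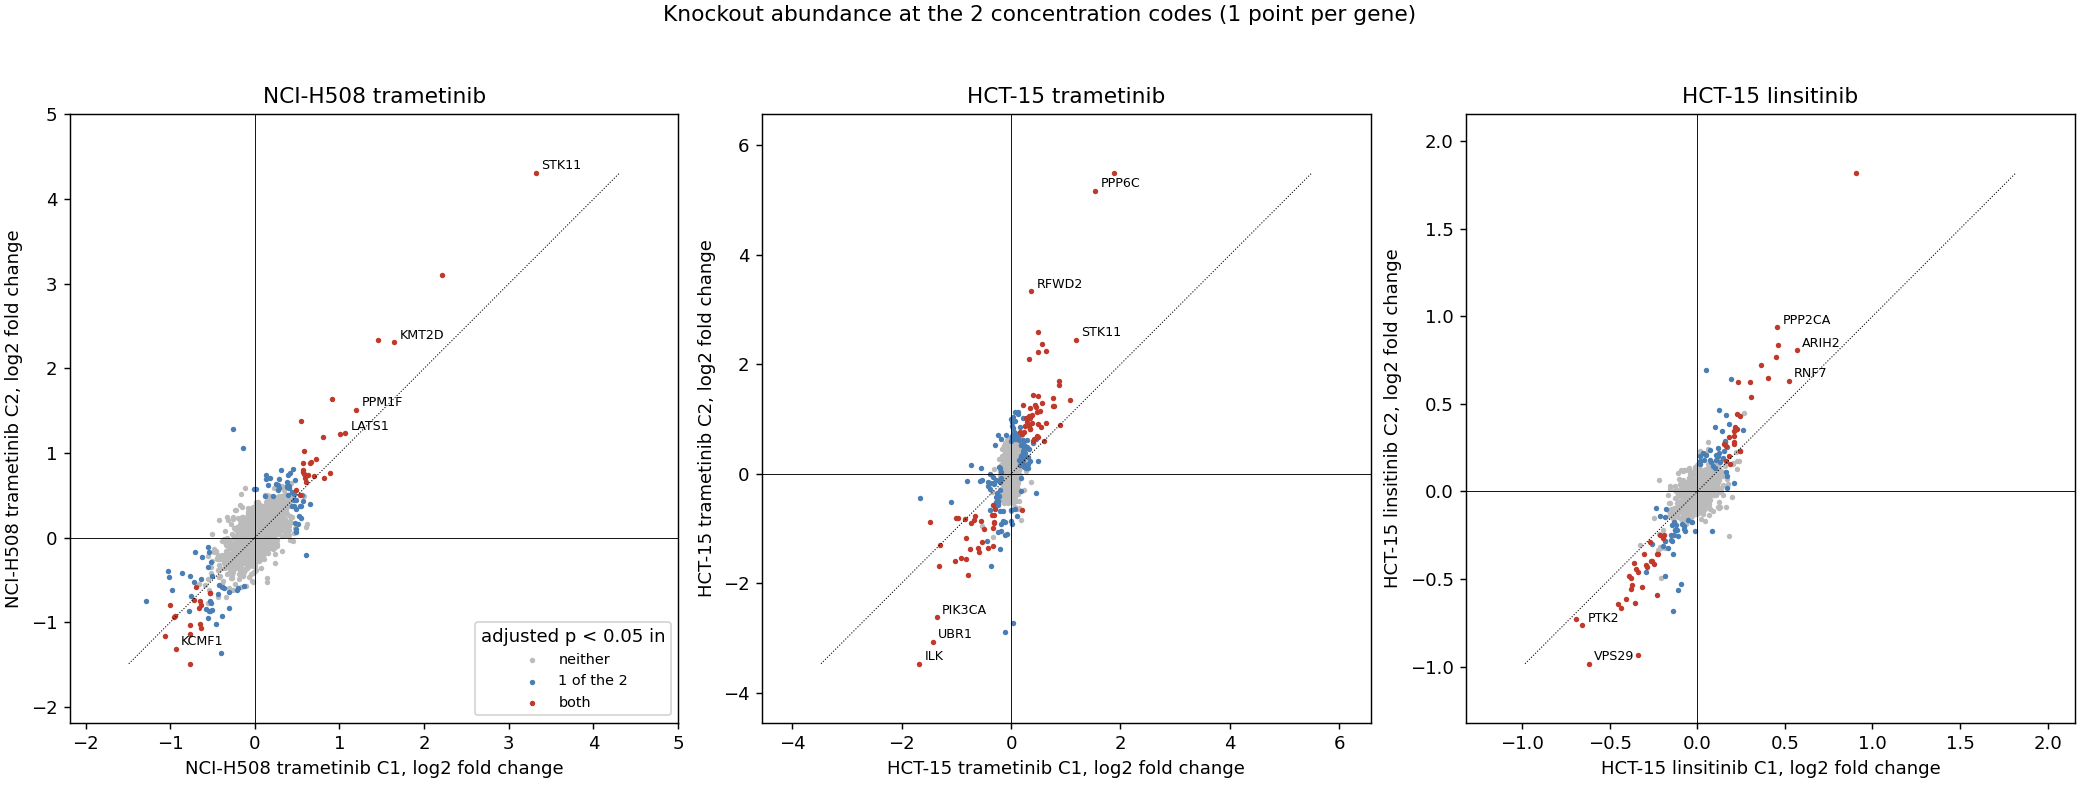
Log2 fold change in the authors' deposited table of each of 1101 knockouts at C1 (horizontal axis) and C2 (vertical axis) for NCI-H508 trametinib, HCT-15 trametinib and HCT-15 linsitinib, coloured by how many of the 2 codes called the gene, with equal values on the dotted line. In the authors' deposited table PPP6C lies at 1.54 and 5.17 in HCT-15 under trametinib, and CSK and MAEA lie near 0 at C1 and at -2.89 and -2.74 at C2.

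Trametinib and linsitinib were compared within HCT-15, where the doses of the 2 drugs cannot be matched. Knockouts of BRAF were lower under trametinib at C1 than under linsitinib, at -1.09 against -0.16 in the authors' deposited table (adjusted p of the difference 2.06e-15). UBR1 knockouts were also lower, at -1.43 against -0.04 at C1 and -3.07 against -0.03 at C2, in the authors' deposited table. PPP6C was higher under trametinib at both codes, at 1.54 against 0.27 and 5.17 against 0.45, in the authors' deposited table. CSK was called in opposite directions at C2, at -2.89 under trametinib and 0.62 under linsitinib (adjusted p of the difference 2.04e-47), in the authors' deposited table.

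At C1, STK11 (1.18 against 0.36), RNF41 (0.90 against 0.10) and DUSP6 (0.50 against -0.05) were higher under trametinib in the authors' deposited table. EGFR (-1.66 against -0.45), PTPN11 (-1.31 against -0.22) and PRKCI (-1.30 against -0.32) were lower in the authors' deposited table. At C2, RFWD2 (3.34 against 0.01), CNOT4 (2.58 against -0.25), DUSP7 (2.23 against 0.06) and SIAH1 (2.25 against 0.11) were higher in the authors' deposited table. PPP1CA was at 1.04 against -0.57, RIPK4 at -1.36 against 0.22, and VRK1 at -1.33 against 0.19 in the authors' deposited table. The test of the z difference called 74 genes at C1 and 76 at C2, and 74 and 40 of them also differed on the log2 scale in the same direction. Division by the robust SD left 48 and 38, with each of the genes named here still called. It ended the calls of other genes selected by the ranking. These were 1 of 16 at C1, PIK3CA, and 4 of 19 at C2, PPM1A, PPP5C, BRAP and CHUK.

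Both drugs called 21 knockouts higher and 24 lower at C1, and 21 and 25 at C2, against 2.50 and 2.04, and 4.00 and 2.83, for independent lists. Opposite calls numbered 3 at C1 and 5 at C2. The fold changes correlated across genes with r of 0.600 at C1 (rho 0.471) and 0.461 at C2 (rho 0.270), with permutation p of 0.0001, the smallest possible. Shared DMSO libraries alone, if DMSO is the reference, gave simulated r of 0.429 and 0.134. The covariances were 0.0155 and 0.0423, against 0.00168 and 0.00184 simulated, and part of the excess may again come from the shared controls or transductions.

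Trametinib was applied to both lines at different doses, and the codes were paired as C1 with C1 and C2 with C2. STK11 and PPM1F knockouts were higher in both lines at both codes. KMT2D knockouts were higher in NCI-H508 and lower in HCT-15 at C1, at 1.64 and -0.56 in the authors' deposited table (adjusted p of the difference 5.92e-33). DYRK1A and CDK8, both on the list of transcriptional kinases, were likewise opposed at C1, at 1.00 and -0.42, and 0.72 and -0.54, in the authors' deposited table. CDK13 on the same list went the other way, at -0.63 and 0.40, in the authors' deposited table. Of the list's 17 members, 2 were higher and 2 lower in NCI-H508 at C1, and 3 higher and 2 lower in HCT-15, without a shift in either line (adjusted permutation p 0.560 and 0.568). Adjusted over the list alone, these counts were 2 and 2, and 4 and 2. GSK3A and GSK3B, which encode both forms of glycogen synthase kinase 3, were lower in NCI-H508 and higher in HCT-15 at C2, at -0.92 and 0.94, and -0.83 and 1.05, in the authors' deposited table. RNF20 and RNF40, partner E3 ligases for histone H2B, were opposed in the same way at C2, at -0.86 and 1.21, and -0.92 and 1.43, in the authors' deposited table.

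Opposite calls between the lines numbered 8 at C1 (BMPR2, CDK13, CDK8, DYRK1A, GSK3B, KMT2D, PKN2 and TRIB1) and 9 at C2 (among them CDK13, GSK3A, GSK3B, MAP2K4, RNF20, RNF40, TRIB1 and WNK1). Each of these differences was itself called on z, and stayed called after division by the robust SD. The genes were chosen for opposite calls on the same z scores, so this largely follows from the selection and adds no separate support. The calls in both lines stayed opposite on that scale for only 4 of the 8 genes at C1 (CDK8, DYRK1A, KMT2D and TRIB1) and for 0 of the 9 at C2. There GSK3A was no longer called in HCT-15, nor were GSK3B, RNF20 and RNF40 in NCI-H508. TRIB1 had -0.95 and 0.27 at C1, and -0.93 and 1.02 at C2, in the authors' deposited table. UBR1 was called in HCT-15 alone, at -1.43 and -3.07 against 0.31 and 0.50 in NCI-H508, in the authors' deposited table. The difference was called at both codes (adjusted p 1.30e-33 and 3.30e-24). PPP6C was lower in NCI-H508 than in HCT-15, at -0.14 against 1.54 at C1 and 1.05 against 5.17 at C2, in the authors' deposited table (adjusted p of the difference 2.67e-14 and 5.39e-34).

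The test of the z difference called 120 genes at C1 (64 higher in NCI-H508, 56 lower) and 81 at C2 (40 higher, 41 lower), of which 70 and 76 also differed on the log2 scale in the same direction. Division by the robust SD left 62 and 36. Pairing C1 of NCI-H508 with C2 of HCT-15 gave 70, and the reverse pairing gave 135. The lines shared 15 higher and 10 lower calls at C1, and 17 and 5 at C2, against 3.36 and 2.10, and 3.73 and 1.70, for independent lists. Fold changes correlated across genes with r of 0.254 at C1 (rho 0.0983) and 0.291 at C2 (rho 0.137). The permutation p was 0.0001, the smallest possible, and the lines share no libraries.

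**Figure D3:**
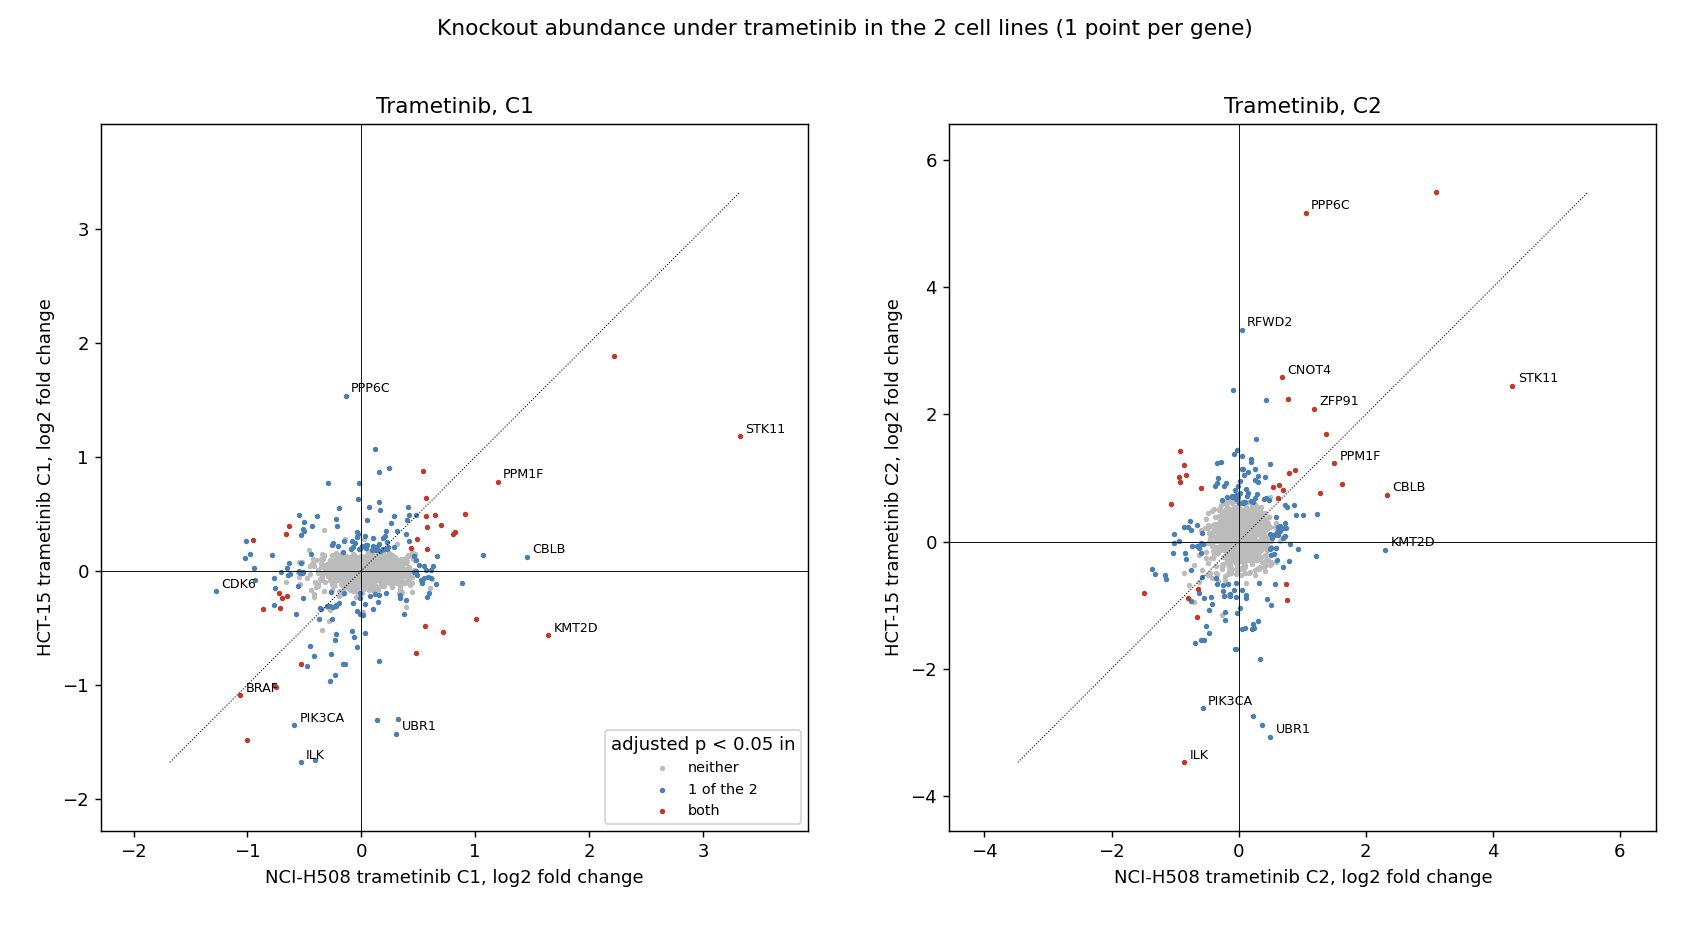
Log2 fold change in the authors' deposited table of each of 1101 knockouts under trametinib in NCI-H508 (horizontal axis) and HCT-15 (vertical axis) at C1 and C2, coloured by how many of the lines called the gene, with equal values on the dotted line. STK11 is high in both lines, KMT2D lies at 1.64 and -0.56 at C1, and PPP6C lies at 1.05 and 5.17 at C2, by the authors' deposited table.

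Across all 6 comparisons, 4 knockouts were called higher in each, among them those of STK11 and TAOK1, and those of PTK2 were called lower in each. TAOK1, a kinase upstream of JNK, p38 and Hippo signalling, ranged from 0.23 to 1.12, in the authors' deposited table. PTK2 ranged from -1.18 to -0.53 in the authors' deposited table. PEX10, PPM1F, PTPN12 and SIAH1 were called higher in 5 of the 6, and ILK and CSNK1A1 lower in 5. TAOK1 was named after its values were seen. The 6 comparisons are not independent, since those within a line share DMSO libraries if DMSO is the reference. After division by the robust SD, STK11 was still called in 6 comparisons, PPM1F in 5, TAOK1, PTK2 and ILK in 4, PTPN12 and CSNK1A1 in 3, and PEX10 and SIAH1 in 2. Of the 1101 genes, 299 were called at least once by the authors' deposited table, 30 of them at least once in each direction.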

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

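Tests of wider errors and of a turned sign were chosen after the results they bear on were seen. The predictions for a scaling shift and for chromosomal neighbours were written before the results of those tests were seen. The scaling test nevertheless uses calls on both scales and centred differences, which were chosen after the data were seen. The differences listed by gene below were singled out because z under trametinib differed between NCI-H508 and HCT-15. That test called 120 genes at C1 and 81 at C2. A difference in z also depends on the error in each line, and 70 and 76 of these also differed on the log2 scale in the same direction. Division of z by its robust SD left 62 and 36. The second pattern weighed below is instead a difference between codes within HCT-15. The doses differ between the lines. Differences are log2 fold changes of NCI-H508 minus HCT-15, from the authors' deposited table.

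At C1 the highest differences were those of KMT2D at 2.21, STK11 at 2.14, UBR1 at 1.74, PRKCI at 1.62, PTPN11 at 1.45, DYRK1A at 1.43, CBLB at 1.33, EGFR at 1.26, CDK8 at 1.26 and BMPR2 at 1.21. The lowest at C1 were PPP6C at -1.68, PTPMT1 at -1.28, TRIB1 at -1.23, RNF8 at -1.14, CDK2 at -1.12, PPP2CA at -1.07, CBLL1 at -1.03, CDK13 at -1.03, GSK3B at -0.98 and GSK3A at -0.96. Only STK11 and PTPMT1 among these lost the call after division of z by its robust SD. The EGFR difference had the other sign at C2, but there it was not called on z, so a reversal between the codes is not shown. EGFR was at -0.40 in NCI-H508, where it was not called, and -1.66 in HCT-15 at C1, against -1.36 and -0.44 at C2. At C2 its z was -3.68 in NCI-H508, a call lost after division by the robust SD. In HCT-15 its z was -1.94 at C2, where it was not called (adjusted p 0.252).

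At C2 the highest differences were those of UBR1 at 3.56, CSK at 3.26, MAEA at 2.97, ILK at 2.61, KMT2D at 2.44, MAP2K3 at 2.17, PIK3CA at 2.06, STK11 at 1.86, WNK1 at 1.69 and ANAPC11 at 1.64. The lowest at C2 were PPP6C at -4.12, RFWD2 at -3.29, PPM1A at -2.47, RNF40 at -2.35, RNF20 at -2.06, TRIB1 at -1.96, CNOT4 at -1.90, GSK3B at -1.88 and GSK3A at -1.87. Only ANAPC11 among these lost the call after division of z by its robust SD.

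Opposite calls in the lines form the first pattern weighed, with 14 genes such as KMT2D, GSK3A, GSK3B, RNF20 and RNF40. After division of z by its robust SD, the calls in both lines stayed opposite for 4 of 8 genes at C1 and for 0 of 9 at C2. The tables argue against a fold change whose sign was turned in 1 line, since z correlated across genes between the lines at 0.290 at C1 and 0.303 at C2, above the highest of 10000 permutations at either code (0.193). Chromosomal neighbours moving together, as line-specific copy number could make them, stay open. The nearest library neighbours had a mean signed line difference of 0.627, against 5.95 for the genes themselves, within the permutation range of -0.729 to 0.738 but above the bound set beforehand as a fraction of the genes' own mean. A response that depends on the line may be the source, which was not tested because line and dose coincide. Whether the lines were also processed separately is not given in the sources used here.

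The second pattern weighed is the set of knockouts that differed between C2 and C1 in HCT-15 under trametinib. Wider errors at C2 could lower z without another response. The tables argue against that for 18 of the 51 genes called on z, which differed on both scales in the same direction. Of these 18, only PPP6C, RFWD2, EGFR, MAP2K5, CSK, MAEA and MAP2K4 stayed called after division of z by its robust SD. Of the other 33, 5 were called in the opposite direction on the log2 scale, among them ILK, RNF7 and STK11. Their fold changes were larger at C2 and their z smaller, so the direction of their z calls arises from the wider errors there. For ILK these were -1.68 (z -17.0) at C1 and -3.47 (z -12.1) at C2. For the 28 called on z alone it stays open, since a difference that misses the threshold on the log2 scale does not show equal fold changes. A shift of all genes at C2 through scaling is also argued against for those 18, since 17 were still called on both scales after centring, PRKD1 being lost. Both tests take errors as independent, and a dose-dependent response stays open as untested because the dose behind each code is not known.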

How the results depend on the processing

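Division of each comparison's z by its robust SD, centring of z in differences, and calls on both scales were chosen after the data were seen. No paired analysis was possible because the values used are 1 summary per gene and comparison with no replicate. For the same reason leaving out replicates, other splits of the samples, count-model and size-factor alternatives, filters on low counts, and guide-level or control-guide alternatives were not run. No called list shift or gene call reversed within a single comparison under any alternative run, and depth is unknown.

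Gene calls, in the order NCI-H508 trametinib C1 and C2, HCT-15 trametinib C1 and C2, and linsitinib C1 and C2, were 77, 90, 154, 128, 65 and 118. With an absolute log2 fold change of at least 1 they were 12, 22, 14, 60, 0 and 1, a filter that favours comparisons with wide errors. At an adjusted p under 0.01 they moved by over 1.5 times only in NCI-H508, to 43 and 59. Division by the robust SD gave 18, 21, 106, 66, 43 and 65, where by construction a wider spread of z lowers the count. Thresholds of 0.1 and centring kept each count within 1.5 times.

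Lists passing were 3 in each comparison and 2 at linsitinib C2. On the median they were 1 for NCI-H508 C2, 0 for HCT-15 trametinib C2 (6 lists at an unadjusted p under 0.05), and 1 and 1 for linsitinib. On the mean fold change they were 5 for NCI-H508 C2, and 6 and 6 for HCT-15 trametinib. Without the most extreme gene 0 passed in each of the 6, with 4, 3, 4, 4, 3 and 3 lists at an unadjusted permutation p under 0.05. The cause was not tested for the median and the fold change.

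Differences between codes were 51 for HCT-15 trametinib, 18 on both scales and 24 after division by the robust SD. Its difference reversed on the log2 scale for ILK at -1.79, RNF7 at 0.75 and STK11 at 1.27, since z is smaller at C2 where the errors are wider. For linsitinib 13 became 23 on the log2 scale and 2 after division, and for NCI-H508 2 became 4 and 0 (4 genes at an unadjusted p under 0.05). Trametinib against linsitinib gave 74 at C1 and 48 after division, and 76 at C2 with 40 on both scales and 38 after division. Lines differed at 120 genes at C1, with 70 on both scales, 62 after division and 70 against the other code in HCT-15. At C2 they differed at 81, with 36 after division and 135 against the other code. Division lowers these counts by construction, and for the others the cause was not tested.

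Among 163 values of the ranked and always named genes, 131 of them called, centring lost 1 call and gained 1. Division by the robust SD lost 18 of these calls and gained 0. Other named values, such as those of list members, are not counted there. Among 111 differences of named genes, the log2 scale kept 106, lost 2 and reversed those 3, centring lost 1, and division lost 34. Most of these genes were named for large log2 differences among genes called on z, so the selection itself favoured keeping them on the log2 scale. Over all genes called on z, that scale kept 18 of 51 between the codes in HCT-15 under trametinib. It kept 40 of 76 between the drugs at C2 and 70 of 120 between the lines at C1. Pairing with the other code lost 8 of 39, and the cause was not tested. Of the 17 list shifts called, 17 were lost without the most extreme gene.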

Other observations

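The tests of neighbouring genes and of effects shared by the lines were set before their results were seen, and the groups in the first 2 paragraphs come from lists fixed beforehand, while the members named were chosen after their values were seen. Knockouts of the stress kinases MAP2K3, MAPK14 and MAP3K2 were lower in HCT-15 under both drugs, while those of TAOK1, on the same list, were higher. MAP2K3, which activates p38, was at -0.80 and -1.84 under trametinib and at -0.23 and -0.59 under linsitinib in the authors' deposited table. MAPK14, the p38-alpha kinase, was at -0.82, -1.55, -0.29 and -0.42, and MAP3K2 at -0.56, -0.86, -0.19 and -0.25, in the authors' deposited table. In NCI-H508 the JNK-activating kinase genes MAP2K4 and MAP2K7 were higher, at 0.58 and 0.75, and 0.49 and 0.56, in the authors' deposited table. As a list of 32 the JNK and p38 cascades passed in no comparison, with adjusted permutation p from 0.150 to 0.620. Its higher and lower members were 3 and 0, 5 and 0, 4 and 6, 5 and 5, 1 and 5, and 2 and 6, and adjusted over the list alone they were 3 and 0, 5 and 1, 4 and 6, 5 and 5, 1 and 5, and 2 and 6.

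Bone morphogenetic protein receptor genes BMPR1A and BMPR2 were lower in HCT-15 under trametinib, at -0.84 and -0.82, and -0.73 and -0.90, in the authors' deposited table. They were the 2 called members of a list of 14 at each code, also 2 adjusted over the list alone, without a list shift (adjusted permutation p 0.346 and 0.677). MDM2 and MDM4, which restrain p53, were higher under linsitinib, at 0.21 and 0.37, and 0.18 and 0.31, in the authors' deposited table. Their list of 11 had 3 higher and 0 lower at each code, with 3 and 1, and 4 and 0, adjusted over the list alone, and did not pass (adjusted permutation p 0.106 and 0.0701). Catalytic subunits of PP1 fell under linsitinib at C2, with PPP1CA at -0.57, PPP1CB at -0.30 and PPP1CC at -0.36, beside a higher PPP2CA at 0.94, in the authors' deposited table. The list of 11 subunits of PP1, PP2A and related phosphatases had 1 higher and 3 lower there, 2 and 3 adjusted over the list alone, and did not pass (adjusted permutation p 0.709). Of these genes, MAP2K7, MAP2K4 in NCI-H508, MDM4 at C1, PPP1CB at C2, and MAP3K2 at HCT-15 trametinib C2 and linsitinib C1 were not called once z was divided by its robust SD. MAP2K3 was not called at linsitinib C1 on that scale either.

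RNF7, a RING subunit that works with CUL5, and ARIH2, an E3 ligase that acts with it, were higher in each of the 4 HCT-15 comparisons. RNF7 was at 0.87, 1.62, 0.52 and 0.63 and ARIH2 at 1.07, 1.35, 0.57 and 0.81 in the authors' deposited table. In NCI-H508 neither was called, by the same authors' deposited table. The 4 HCT-15 comparisons share DMSO libraries if DMSO is the reference, so they are not independent repeats.

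The spread of z among the 802 genes called in no comparison was above 1 in each, with SDs of 1.15, 1.16, 1.05, 1.10, 1.02 and 1.08 although called genes were left out. Small real effects shared by the lines might widen it. Across these genes z correlated between the lines at 0.0415 at C2 (permutation p 0.24) and 0.00324 at C1 (permutation p 0.93). Both lay under the bound of 0.05, which met the condition set beforehand for arguing against shared effects. The upper 95% limits of 0.110 and 0.0725 did not lie under 0.05, a stricter requirement that was not part of that condition. Because of these limits the explanation is left open here. Chromosomal neighbours moving together, as copy number or cutting load would make them, stay open too. The correlation of z over 577 neighbour pairs lay within its permutation range in 4 of 6 comparisons, those of HCT-15, and above it in NCI-H508, at 0.156 and 0.149 against upper ends of that range of 0.0796 and 0.0819.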
